A study of Xenopus laevis with 28 samples.

How the data were processed

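Whole tissue was minced, RNA was extracted with TRIzol and column purified, and libraries were made after poly-A capture without strand information for the HiSeq 2000, per the labels' protocols. Groups were the 14 tissues, and the replicate number was the dataset, Taira for 1 and Ueno for 2, per the labels. The submitters' processing notes name BWA 0.7.10 and RSEM 1.2.19, and per the labels the reference was a set of cDNA models. The authors deposited 1 table of TPM values, in which each library sums to 1000000 within rounding, so TPM is a share of a library and a gene can fall because others rise. TPM keeps no read depth, so no counting interval could be given and no count model was used. All columns of the table were mapped to a sample by name.

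Models with a TPM of at least 1 in at least 2 of the 28 libraries were kept (33317 of 45831, with 5050 at 0 in all libraries). The values were put on the log2(TPM + 1) scale and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per tissue, 28 libraries and 14 residual degrees of freedom, and moderated variances with a mean trend. A model was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1 in size. Contrasts were each tissue against the mean of the other 13, testis against ovary, heart against muscle, stomach against intestine and brain against eye. Adjusted p-values in the text are from limma unless another test is named. The frogs were compared as Ueno minus Taira over the 26 libraries of female tissues with tissue as a block. Homeolog pairs were symbols that occur once with the ending L and once with the ending S (8017 pairs, 7749 of them tested, with at least 1 copy past the minimum). Their log2 ratio per library, with 1 TPM added to each copy, was tested for a mean over tissues different from 0, and by an F test for differences between tissues. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the table.

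The replicates come from separate animals, 1 per dataset, so p-values within tissues rest on 2 animals, and dataset, date code and clutch cannot be told apart. Among the 13 female tissues the donor goes with them. Samples with the same number come from the same female for 13 tissues, per the series design, so the numbers pair the samples. As a check, the Ueno minus Taira differences of 2 female tissues correlated across genes with a median r of 0.425 over 78 pairs of tissues (lowest -0.0138, highest 0.723, and 74 over 0.1). The main fit did not use this pairing. The fit with the frog as a block, that is the dataset with testis included, was an alternative.

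Gene lists were fixed before the data were examined: 1 list for each of the 14 organs, and lists for erythrocyte, macrophage and granulocyte, endothelium, smooth muscle, fibroblast and matrix, adipocyte, ciliated cell, cell division, cytosolic ribosomal protein, mitochondrial ribosomal protein, proteasome, oxidative phosphorylation, glycolysis, spliceosome, translation initiation, DNA replication and repair, homeobox cluster, signalling ligand and receptor, and complement and interferon response, 33 in all. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over all lists and contrasts of its family. Named genes followed a rule fixed at the same time: the 5 genes with the largest difference per tissue among called models whose libraries are both above all others, the next 3 called and up to 2 uncalled members of the tissue's own list, 10 per direction for testis against ovary, 6 per direction for the other pairs of organs and the frogs, and 8 pairs per direction with a summed mean TPM of at least 10 for the homeologs, and the 8 pairs whose ratio swung most between tissues. Genes of the organ pairs had to have libraries that do not overlap, and those of the frogs had to go the same way in all 13 female tissues. Symbols that are placeholders were not named.

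The fits were tested on simulated data with 200 changed models. In the tissue contrast on 33317 models, 45.5% were recovered at a log2 change of 1.5, 67% at 2 and 86% at 3. In an organ pair these were 20%, 35% and 67%, and in the comparison of the frogs 83%, 94.5% and 97.5%. All 200 of 7749 simulated pairs were recovered at each size, and at most 9 models were called falsely in any run. The simulated noise was independent between libraries with 1 spread per model, as the fit assumes. Donors shared by tissues and spreads that differ between tissues were not simulated, so these runs cannot give the rate of false calls in the data. Alternatives were pseudocounts of 0.1 and 5, no filter, a TPM minimum of 5, median-of-ratios scaling, quantile normalization, the frog as a block, no variance trend, the gonads left out of the other tissues, both copies past the minimum, testis added to the comparison of the frogs, and each of the 28 libraries left out in turn, the other library of that tissue being assumed to vary like the other tissues. Transcript length was not tested. Models without a symbol entered every count and were not named. Genome coordinates were not used here.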

Results

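Polyadenylated RNA was sequenced from 14 adult tissues of the inbred J strain of Xenopus laevis, the African clawed frog, an allotetraploid whose genome carries a long (L) and a short (S) copy of many genes. Each tissue had 2 libraries, 28 in all. Replicate 1 came from the Taira dataset and replicate 2 from the Ueno dataset. For 13 tissues each dataset used 1 female donor, and the testis libraries came from 2 male siblings of those females. The deposited table gave 45831 gene models as TPM, the share of a library's transcripts that came from a model, scaled to a total of 1000000, of which 20523 had no gene symbol, and 33317 reached a TPM of 1 in at least 2 libraries. Each library summed to between 999999 and 1000001 TPM, so the read depth behind a value is unknown. The number of models above 0 ranged from 24533 to 34388 per library. The 10 most abundant models took 1.52% of the TPM in ovary replicate 1 and 62.8% in each pancreas library. All 28 libraries correlated best with the other library of their own tissue, with Pearson's r across genes from 0.847 in ovary to 0.954 in skin, against at most 0.85 between different tissues. Genes are not independent replicates, so these r values only describe the libraries. Values below are mean TPM ± SD of the 2 libraries of a tissue unless stated, symbols are those of the table with the copy after the point, and differences are on the log2(TPM + 1) scale, which understates changes of low genes.

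The first question was which genes each tissue expressed above the mean of the other 13 tissues. The 5 tissues with the most models called higher were brain (11812), ovary (7850), testis (6267), eye (5898) and spleen (5222), and pancreas had the fewest (275). Between these lay kidney with 4640, intestine with 3561, lung with 2797, heart with 2653, skin with 2627, muscle with 1860, liver with 1408 and stomach with 1294. In 14 of 14 tissues most of these genes were higher by at least 1 in each dataset taken alone, for example 10568 in brain and 242 in pancreas. The calls rest on the same libraries, so this agreement is partly built in. Models called lower ran from 359 in kidney to 17541 in pancreas, where a few secreted enzymes fill most of the TPM. The median model differed by 0.72 in brain, 0.40 in kidney, 0.22 in eye, 0.16 in spleen, 0.01 in testis, -0.08 in lung, -0.13 in intestine, -0.17 in skin, -0.18 in heart, -0.23 in ovary, -0.50 in stomach, -0.66 in muscle, -0.67 in liver and -1.33 in pancreas. After median-of-ratios scaling all 14 medians lay between -0.09 in brain and -0.34 in ovary, and the share of higher among all calls changed from 90.1% to 64.5% in brain, from 17.7% to 52% in liver, from 18.5% to 47.4% in muscle, from 1.54% to 54% in pancreas and from 27.1% to 65.6% in stomach. It changed from 90.5% to 79.2% in eye, from 92.8% to 80.4% in kidney, from 54.8% to 42.4% in ovary, from 69.3% to 51.7% in spleen and from 71.3% to 51.8% in testis. Under quantile normalization the share was 51.2% in brain, 61.1% in eye, 70.3% in kidney, 55.8% in liver, 52.5% in muscle, 59% in pancreas, 54.2% in spleen, 64.5% in stomach and 52.5% in testis. The scaled counts of higher models were 5888 in brain, 2377 in kidney, 2825 in liver, 3778 in muscle, 1513 in pancreas, 3272 in spleen and 2141 in stomach. Leaving out 1 library lowered the count by more than 1.5 times in 9 tissues: to 1386 without heart replicate 1, 2276 without intestine replicate 1, 2669 without kidney replicate 1, 1237 without lung replicate 1, 1204 without muscle replicate 2, 1683 without skin replicate 2, 2798 without spleen replicate 1, 770 without stomach replicate 1 and 3975 without testis replicate 1. A pseudocount of 5 instead of 1 gave 7849 in brain, 3156 in eye, 2645 in kidney, 1785 in lung, 167 in pancreas, 1706 in skin, 3244 in spleen and 722 in stomach.

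**Figure D1:**
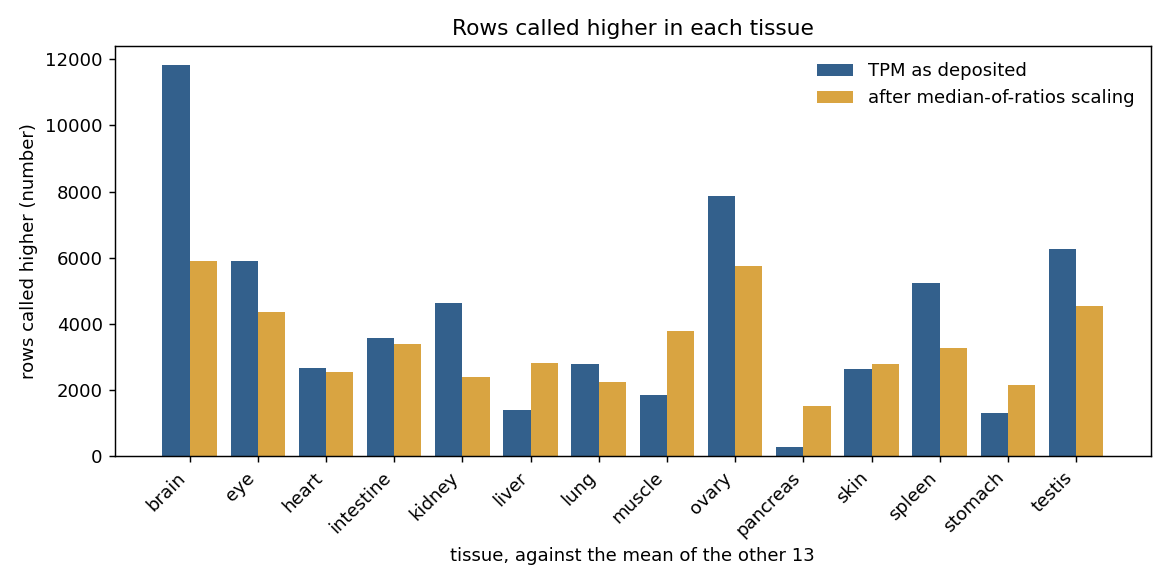
Number of gene models called higher (y axis) in each of the 14 tissues (x axis) than in the mean of the other 13, from TPM as deposited (blue bars) and after median-of-ratios scaling (yellow bars). Brain fell from 11812 to 5888 and pancreas rose from 275 to 1513.

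In brain the prolactin gene prl.1.S (Xelaev18033507m) stood at 2223 ± 1442 TPM against a mean of 0.237 in the other tissues (log2 difference 10.78, SE 0.32, adjusted p = 6.6e-15). The proopiomelanocortin gene pomc.L, the vasopressin and oxytocin precursor genes avp.S and oxt.S and the myelin basic protein gene mbp.S followed, with log2 differences of 9.40 to 10.52. The fixed brain list, of neuronal, glial and pituitary genes, rose in 42 of 44 measured models, also 42 when adjusted over the list alone, with a median of 6.86 (camera adjusted p = 1.77e-28). Examples were the synaptic gene snap25.L at 1080 ± 261 TPM and the growth hormone gene gh1.L at 339 ± 326 TPM, which was listed at 0 in the other tissues. Pituitary genes were uneven between the brains: gh1.L stood at 109 TPM in the Taira and 569 TPM in the Ueno brain, and pomc.L at 5039 and 459 TPM. How much pituitary the samples held was not tested. The model gad1.2.L was listed at 0 in both brain libraries and stood at 275 TPM in the Taira and 5.54 TPM in the Ueno ovary.

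The leading genes of eye encode lens crystallins and photoreceptor proteins. The crystallin crybb2.S (Xelaev18010412m) reached 29506 ± 14558 TPM against 1.31 elsewhere (log2 difference 14.10, SE 0.45, adjusted p = 2.52e-14), and crybb3.L and cryba1.L differed by 12.44 and 12.07. The rod transducin gene gnat1.L stood at 3676 ± 741 TPM and the retinoid carrier gene rbp3.L at 2531 ± 387 TPM. Of the eye list, 52 of 53 models rose (52 adjusted over the list alone, median 7.77, camera adjusted p = 1.9e-70), and rpe65.S did not (log2 difference 0.34, adjusted p = 0.124). Lists made for other tissues also rose in the eye libraries, and the source of these transcripts was not tested. The muscle list rose in 22 of 28 models (23 adjusted over the list alone, median 2.86, camera adjusted p = 2.6e-10), and the skin list in 21 of 30 models (21 adjusted over the list alone, median 2.44, camera adjusted p = 6.58e-10). With an estimated correlation these calls were lost (adjusted p = 0.0956 for muscle and adjusted p = 0.183 for skin). Of the muscle list 23 models in the Taira and 21 in the Ueno eye lay at least 1 above the other tissues of that dataset, and of the skin list 28 and 18. The fast muscle light chain mylpf.L stood at 552 ± 83.2 TPM in eye. Skin genes were uneven between the eyes: the keratin krt5.6.S stood at 2078 TPM in the Taira and 531 TPM in the Ueno eye, krt6.L at 541 and 0.4 TPM and anxa8.S at 354 and 17.8 TPM.

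The leading gene of heart, the light chain myl3.S (Xelaev18032758m), stood at 26861 ± 3965 TPM against 0.983 elsewhere (log2 difference 14.20, SE 0.31, adjusted p = 1.83e-15). The light chain myl7.S (20817 ± 1041 TPM), the atrial peptide gene nppa.L (12221 ± 4511 TPM) and the troponin genes tnni3.S and tnnc1.L differed by 11.74 to 13.75. The heart list rose in 26 of 31 models (26 higher and 1 lower adjusted over the list alone, median 6.58, camera adjusted p = 4.53e-49). Members ankrd1.L and myh7.S were at 1.90 and 0.535 TPM, with log2 differences of 0.30 and 0.05 that did not pass. In muscle the fast light chain gene mylpf.L (Xelaev18045645m) stood at 21128 ± 6970 TPM against 45.5 elsewhere (log2 difference 12.45, SE 0.77, adjusted p = 1.11e-09). The calcium buffer gene pvalb.1.S varied widely between the frogs, at 25835 ± 31052 TPM. The troponin gene tnnc2.L, the creatine kinase gene ckm.S and the ribosomal protein gene rpl3l.L differed by 10.09 to 11.21. The muscle list rose in 26 of 28 models and fell in 2 (26 and 2 adjusted over the list alone, median 8.02, camera adjusted p = 1.71e-65). The 2 that fell were the copies of the glycogen phosphorylase gene pygm, of which pygm.L stood at 2.68 ± 0.085 TPM in muscle and 431 TPM in brain.

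Intestine and stomach expressed digestive genes. In intestine the metalloprotease mmp1.L (Xelaev18013828m) stood at 4645 ± 245 TPM against 0.195 elsewhere (adjusted p = 4.52e-15), and the fatty acid carrier gene fabp2.S at 3463 ± 136 TPM. The brush border protease mep1a.L, the amino acid transporter slc6a19.L and the apolipoprotein apoa1.S differed by 9.91 to 10.31. The intestine list rose in 27 of 30 models (27 adjusted over the list alone, median 6.84, camera adjusted p = 5.25e-38). In stomach the pepsinogen gene pga4.1 (Xelaev18000052m) stood at 29789 ± 10935 TPM against 2.20 elsewhere (log2 difference 14.04, SE 0.97, adjusted p = 1.17e-08). It was followed by gkn1.L (8413 ± 1415 TPM), pgc-like.1.1, s100p.L and the intrinsic factor gene gif.L. The stomach list rose in 15 of 16 models (15 adjusted over the list alone, median 6.56, camera adjusted p = 3.8e-54), among them the proton pump subunit atp4b.S at 1858 ± 1699 TPM. The stomach list also rose in intestine, in 10 of 16 models, and fell in 2 (10 and 2 adjusted over the list alone, median 2.86, camera adjusted p = 9.1e-05, and adjusted p = 0.0956 with an estimated correlation). In stomach sult1c2.1 did not pass (log2 difference 0.21, adjusted p = 0.748).

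The leading genes of pancreas and liver encode secreted proteins. In pancreas the protease ctrc.L (Xelaev18036440m) alone stood at 110975 ± 9615 TPM (log2 difference 15.28, SE 1.05, adjusted p = 1.34e-08), and ela1.L, ctrb2.L, prss1-like.2.L and cela1-like.1.L lay between 45474 and 69443 TPM. The pancreas list rose in 16 of 19 models (16 adjusted over the list alone, camera adjusted p = 9.31e-82), with a median of 2.99 that became 5.38 after scaling. In liver alb-like.1.S (Xelaev18009507m) averaged 20437 ± 28283 TPM, from 40437 TPM in the Taira and 438 TPM in the Ueno liver (log2 difference 11.36, SE 1.21, adjusted p = 2.5e-06). The fibrinogen genes fgg.L and fgb.L, serpina3k.L and avd.2.L differed by 9.79 to 10.80. The liver list rose in 34 of 35 models (34 adjusted over the list alone, median 5.92, camera adjusted p = 3.5e-92). The prothrombin gene f2.L (1283 ± 357 TPM) and the protein C gene proc.S (415 ± 3.49 TPM) varied little between the frogs, while fga.L (2623 ± 3547 TPM) varied more than its mean.

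In kidney the ion pump regulator fxyd2.L (Xelaev18035445m) stood at 3842 ± 1102 TPM against 5.12 elsewhere (log2 difference 11.18, SE 0.37, adjusted p = 1.59e-13). The enzyme genes agxt.L (6109 ± 1628 TPM) and aadat.L, tmem27.L and fcn2.1 differed by 8.95 to 11.17. The kidney list rose in 24 of 30 models (24 higher and 1 lower adjusted over the list alone, median 4.11, camera adjusted p = 5.24e-23), with slc5a2.L, a glucose transporter, at 640 ± 464 TPM. The water channel aqp2.L was at 0.015 TPM in kidney and 53.4 ± 45.3 TPM in skin. The ovary list also rose in kidney, in 31 of 43 models (32 adjusted over the list alone, median 1.65, camera adjusted p = 1.13e-14, and adjusted p = 0.0566 with an estimated correlation). Of the 4640 models called higher in kidney, 810 had their highest value in an ovary library. Without them 3830 remained.

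**Figure D2:**
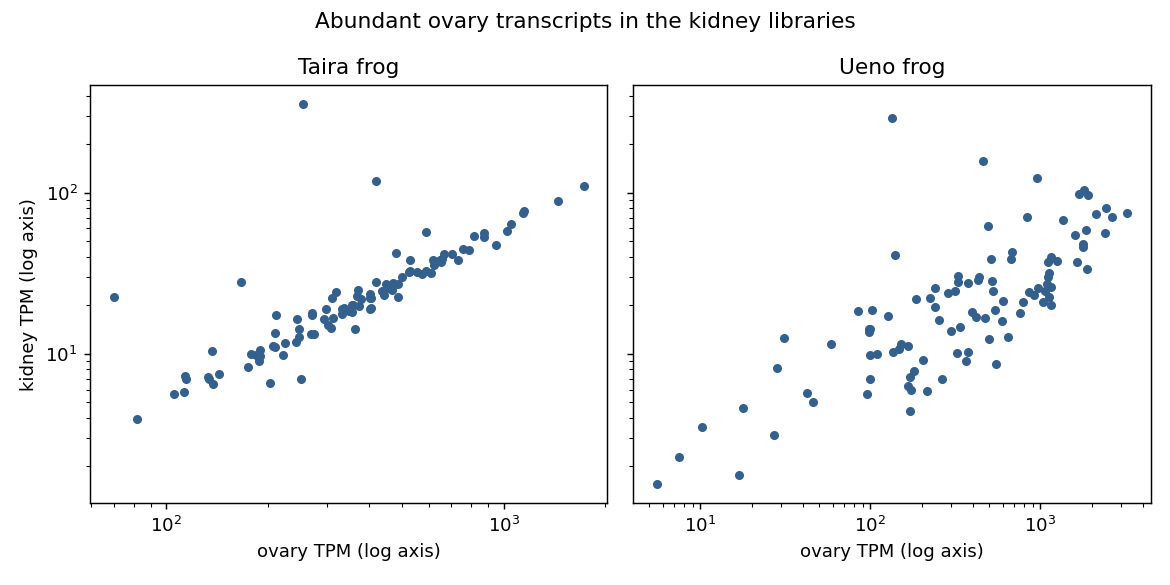
Kidney TPM (y axis, log scale) against ovary TPM (x axis, log scale) for 101 transcripts that averaged at least 100 TPM in ovary and stayed under 1% of that in each of the 12 other tissues, with 1 panel per frog and 1 point per transcript. The median kidney value was 5.63% of ovary in the Taira frog and 5.03% in the Ueno frog.

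In lung the surfactant protein sftpc.S (Xelaev18020193m) stood at 40446 ± 9925 TPM against 4.37 elsewhere (log2 difference 14.15, SE 0.36, adjusted p = 3.55e-14), and sftpb.L at 3510 ± 163 TPM. The next genes, cst7.S, gprc5a.S and fam64a.L, differed by 6.38 to 6.74. Of the lung list only 6 of 14 models rose and 1 fell (6 and 1 adjusted over the list alone). Its median was -0.54 although its mean was 3.17 and the test was positive (camera adjusted p = 0.000564, and adjusted p = 0.138 with an estimated correlation). The models that rose were the copies of sftpc and sftpb, the regulator nkx2-1.L and the water channel aqp5.S, and rtkn2.L fell by 1.44. In skin the keratin krt6.L (Xelaev18013611m) stood at 5323 ± 4298 TPM (log2 difference 11.49, SE 1.14, adjusted p = 6.84e-07). The water channel aqp8.L, anxa8.S, the thyrotropin-releasing hormone gene trh.L and ly6g6d.S had log2 differences of at least 8.60. The skin list rose in 23 of 30 models and fell in 1 (24 rose adjusted over the list alone, median 4.48, camera adjusted p = 2.24e-23). The pigment cell gene dct.L was the model that fell, by 1.81, and without the gonads among the other tissues its difference no longer passed (-0.87, adjusted p = 0.0809). In spleen the chemokines CCL19.L (Xelaev18008528m, 1952 ± 394 TPM, log2 difference 7.37, SE 0.81, adjusted p = 2.39e-06), CXCL13b.L, CXCL8b.L and CXCL13a.S led with ctgfl.L. The spleen list of lymphocyte genes rose in 37 of 38 models (38 adjusted over the list alone, median 4.07, camera adjusted p = 3.08e-29, and adjusted p = 0.1 with an estimated correlation). The exception, irf4.S, had a log2 difference of 1.37 (adjusted p = 0.0531), which passed with the frog as a block (adjusted p = 0.011).

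Ovary expressed oocyte genes and testis expressed sperm genes. The egg coat gene zp4.S (Xelaev18020029m) stood at 1660 ± 1107 TPM in ovary against 5.47 elsewhere (log2 difference 9.87, SE 0.38, adjusted p = 9.73e-13). The genes grhpr.2.L, cldn6.1.L, the pluripotency factor pou5f3.3.L and the cyclin ccna1.L differed by 9.28 to 9.74. The ovary list rose in 37 of 43 models (37 adjusted over the list alone, median 5.98, camera adjusted p = 4.72e-26). For zp4.S, grhpr.2.L, cldn6.1.L and pou5f3.3.L the next highest tissue was kidney, at 68.5, 86.8, 48.8 and 39.5 TPM. In testis the linker histone h1fx.S (Xelaev18025910m) stood at 21028 ± 13352 TPM against 1.68 elsewhere (log2 difference 13.19, SE 0.70, adjusted p = 9.39e-11). The model rflcii.1 averaged 43865 ± 58951 TPM, and rflcii.L, car1_predicted.S and fancd2os.L differed by 9.52 to 12.01. All 30 measured models of the testis list rose (30 adjusted over the list alone, median 5.13, camera adjusted p = 1.35e-25), among them the sex regulator dmrt1.L at 257 ± 49.3 TPM.

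**Figure D3:**
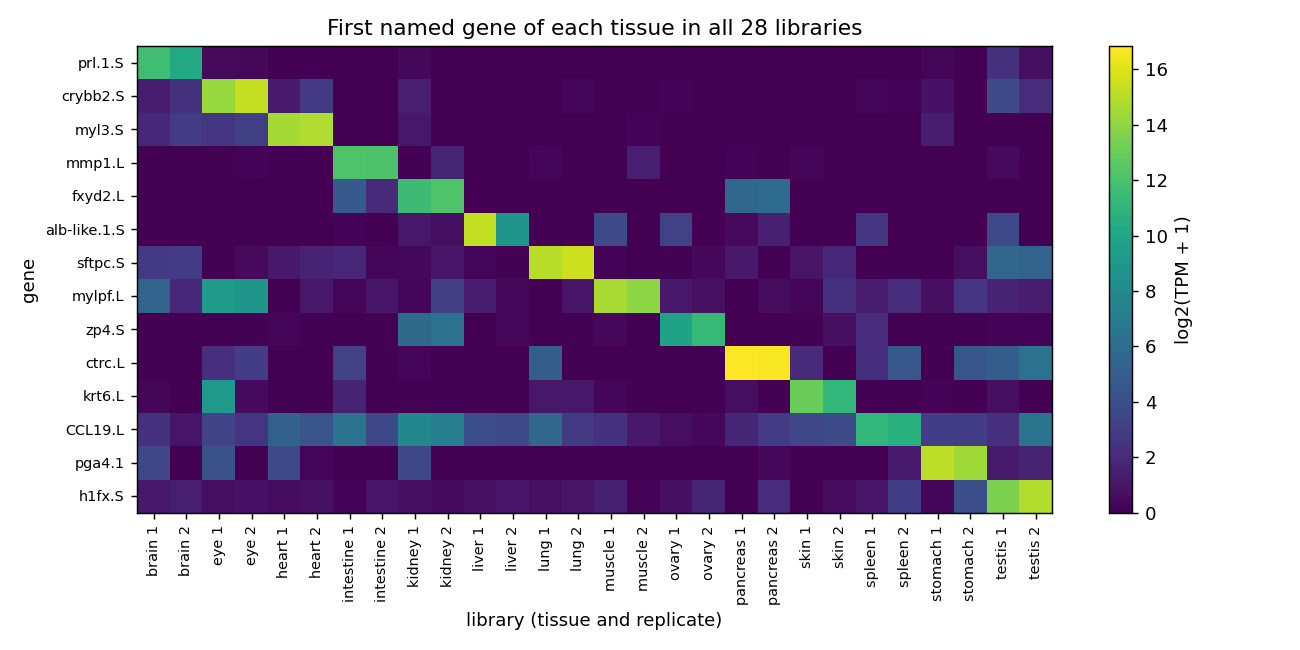
Level of the leading named gene of each tissue (rows) in each of the 28 libraries (columns, tissue and replicate), coloured by log2(TPM + 1). Each gene is bright in its own pair of libraries. Elsewhere values above 6 belong to mylpf.L in eye, krt6.L in eye replicate 1, CCL19.L in kidney, intestine replicate 1 and testis replicate 2, zp4.S in kidney replicate 2 and ctrc.L in testis replicate 2.

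Lists that were not made for 1 organ also differed between tissues. Cell division genes rose in 26 of 26 models in ovary (camera adjusted p = 2.55e-22) and 24 of 26 in testis (camera adjusted p = 1.48e-15, and adjusted p = 0.0669 with an estimated correlation), and fell in 22 of 26 in muscle (camera adjusted p = 1.68e-07, and adjusted p = 0.192 with an estimated correlation). DNA replication and repair genes rose in 62 of 82 models in ovary (camera adjusted p = 1.16e-14, and adjusted p = 0.232 with an estimated correlation). Oxidative phosphorylation genes rose in 81 of 91 models in muscle (camera adjusted p = 1.55e-54, and adjusted p = 0.1 with an estimated correlation) and in 78 of 91 in heart (camera adjusted p = 3.6e-37, and adjusted p = 0.169 with an estimated correlation). Erythrocyte genes rose in 9 of 11 models in liver (camera adjusted p = 1.91e-20) and 10 of 11 in lung (camera adjusted p = 1.27e-14). Smooth muscle genes rose in 6 of 10 models in stomach (camera adjusted p = 2.98e-07). Of the endothelium list 16 of 23 models rose in lung (camera adjusted p = 1.37e-08), of the fibroblast and matrix list 15 of 20 in lung (camera adjusted p = 5.35e-10) and of the macrophage and granulocyte list 8 of 8 in spleen (camera adjusted p = 8.19e-08). With an estimated correlation these 3 had an adjusted p = 0.303, an adjusted p = 0.216 and an adjusted p = 0.102. Homeobox cluster genes rose in 33 of 49 models in kidney (camera adjusted p = 6.35e-16, and adjusted p = 0.0956 with an estimated correlation). None of these medians changed sign under median-of-ratios scaling or quantile normalization. Counts adjusted over the list alone were 26 in ovary and 24 in testis for cell division (25 lower in muscle), 63 for DNA replication and repair, 83 in muscle and 90 in heart for oxidative phosphorylation, 10 in liver and 10 in lung for erythrocyte, 6 for smooth muscle, 19 for endothelium, 15 for fibroblast and matrix, 8 for macrophage and granulocyte and 33 for homeobox cluster. In all, 275 of the 462 list and tissue combinations passed with the preset correlation and 25 with an estimated one.

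Testis and ovary, the gonads of the 2 sexes, were compared directly. In testis h1fx.S, rflcii.1, rflcii.L, car1_predicted.S, fancd2os.L, tubal3.L, tcte1.L, c9orf9.L, fgfbp3.L and fbxo24.L were higher by 8.30 to 12.98. In ovary zp4.S, grhpr.2.L, cldn6.1.L, pou5f3.3.L, avd.2.L, foxh1.L, cldn6.2.L, tuba4.L, ccnb5.L and birc5.1.S were higher, with testis minus ovary from -10.35 to -8.83. The tubulin gene tubal3.L stood at 668 ± 77.2 TPM in testis and was listed at 0 in both ovary libraries (adjusted p = 7.96e-16). Of the ovary list 34 of 43 models were lower and 4 higher in testis (34 and 4 adjusted over the list alone, camera adjusted p = 3.63e-28), and of the testis list 23 of 30 were higher and 2 lower (24 and 2 adjusted over the list alone, camera adjusted p = 3.98e-13, and adjusted p = 0.118 with an estimated correlation). Ciliated cell genes were higher in testis in 12 of 17 models (13 adjusted over the list alone, camera adjusted p = 2.72e-07, and adjusted p = 0.115 with an estimated correlation), and cell division genes were lower in 15 of 26 (17 adjusted over the list alone, camera adjusted p = 4.89e-11, and adjusted p = 0.118 with an estimated correlation). The median model stood at 0.15, and at 0.14 after scaling. Smooth muscle genes were also higher in testis, in 7 of 10 models (9 adjusted over the list alone, median 4.60, camera adjusted p = 5.82e-05, and adjusted p = 0.115 with an estimated correlation), as were fibroblast and matrix genes, in 9 of 20 (9 adjusted over the list alone, median 1.72, camera adjusted p = 0.0121, and adjusted p = 0.89 with an estimated correlation). The fit shared 1 spread per model over all tissues, but the 2 libraries of a tissue differed most in these organs. Across models the SD of Ueno minus Taira was 1.41 in ovary and 1.21 in testis, and at most 0.955, in liver, elsewhere. P-values and counts of the gonads, here and against the other 13 tissues, are thus likely too favourable. In all 4893 models were higher in testis and 4041 in ovary, 4073 and 3653 of them by at least 1 in each dataset. Without testis replicate 1 the first count was 2935 and with a pseudocount of 5 it was 2786, and the animals of the 2 organs differed in sex as well as in organ.

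Heart and muscle, both striated, were compared directly. The genes myl3.S, myl7.S, tnni3.S, nppa.L, the myosin myh15.L and nppb.S were higher in heart by 11.36 to 14.61, and myl7.S, tnni3.S, nppa.L and nppb.S were listed at 0 in both muscle libraries, as tnnc2.L was in heart. The genes mylpf.L, pvalb.1.S, tnnc2.L, rpl3l.S, myoz1.L and pgam2.S were higher in muscle, with heart minus muscle from -13.79 to -10.16. The muscle list was lower in heart in 23 of 28 models and higher in 2 (26 and 2 adjusted over the list alone, camera adjusted p = 2.61e-62) and the heart list higher in 25 of 31 and lower in 5 (25 and 6 adjusted over the list alone, camera adjusted p = 7.07e-24). Erythrocyte genes were also higher in heart, in 5 of 11 models (9 adjusted over the list alone, median 2.65 and 1.69 after median-of-ratios scaling, camera adjusted p = 0.000444, and adjusted p = 0.365 with an estimated correlation). So were the macrophage and granulocyte list in 3 of 8 (3 adjusted over the list alone, camera adjusted p = 0.0161, and adjusted p = 0.695 with an estimated correlation) and the spleen list in 5 of 38 (5 adjusted over the list alone, camera adjusted p = 0.0189, and adjusted p = 0.973 with an estimated correlation). In all 3337 models were higher in heart and 821 in muscle. After median-of-ratios scaling the counts were 1876 and 1759, so that the share higher in heart went from 80.3% to 51.6% (52.9% under quantile normalization) and the median model from 0.40 to 0. With the frog as a block 5301 were higher in heart, and with a pseudocount of 5 the count was 1821. The count was 1471 without heart replicate 1, 1696 without muscle replicate 1 and 2194 without muscle replicate 2.

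Stomach and intestine were compared as parts of the gut. Stomach had more of pga4.1, pgc-like.1.1, atp4b.S, the disulfide isomerase pdia2.L, pgc-like.2.S and gif.L, by 9.23 to 14.81, the first 3 being listed at 0 in both intestine libraries. Intestine had more of mmp1.L, fabp2.S, slc6a19.L, mep1a.L, the water channel aqp10.L and apoa1.S, with stomach minus intestine from -12.18 to -10.02. The intestine list was lower in stomach in 27 of 30 models (27 adjusted over the list alone, camera adjusted p = 1.26e-47) and the stomach list higher in 10 of 16 and lower in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 4.96e-29). Lymphocyte genes of the spleen list were lower in stomach in 18 of 38 models (25 adjusted over the list alone, camera adjusted p = 5.57e-11, and adjusted p = 0.539 with an estimated correlation), as was the macrophage and granulocyte list in 3 of 8 (4 adjusted over the list alone, median -1.90, camera adjusted p = 0.00764, and adjusted p = 0.61 with an estimated correlation). Counts were 543 higher in stomach and 2659 in intestine, and 999 and 1818 after median-of-ratios scaling, a share of 17% against 35.5% (40% under quantile normalization), with the median model at -0.34 and 0. With a pseudocount of 5 the first count was 343, and under quantile normalization the counts were 1148 and 1723. The second count was 1671 without intestine replicate 1 and 1737 without stomach replicate 2.

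Brain and eye, which share neural tissue, were compared directly. Brain had more of prl.1.S, pomc.S, avp.S, oxt.L, the glycoprotein hormone gene cga.S and gh1.L, by 7.97 to 10.56. Eye had more of crybb2.L, crybb3.L, cryba1.L, crybb1.S, gnat1.L and the skin keratin krt5.6.L, with brain minus eye from -13.09 to -10.05. The brain list was higher in brain in 39 of 44 models and lower in 2 (40 and 2 adjusted over the list alone, camera adjusted p = 9.09e-29) and the eye list lower in 51 of 53 and higher in 1 (52 and 1 adjusted over the list alone, camera adjusted p = 1.54e-88). The muscle list was lower in brain in 20 of 28 models and higher in 2 (21 and 2 adjusted over the list alone, camera adjusted p = 3.58e-15) and the skin list lower in 20 of 30 and higher in 1 (21 and 1 adjusted over the list alone, camera adjusted p = 3.75e-18, and adjusted p = 0.0927 with an estimated correlation). Also lower in brain were the fibroblast and matrix list in 6 of 20 models (10 adjusted over the list alone, median -2.41, camera adjusted p = 1.47e-06, and adjusted p = 0.539 with an estimated correlation) and the smooth muscle list in 4 of 10 (4 adjusted over the list alone, median -1.30, camera adjusted p = 0.000621, and adjusted p = 0.159 with an estimated correlation). Homeobox cluster genes were higher in brain in 25 of 49 models (25 adjusted over the list alone, camera adjusted p = 3.25e-05, and adjusted p = 0.576 with an estimated correlation). Counts were 5173 higher in brain and 2152 in eye, and 2986 and 2519 after median-of-ratios scaling, a share of 70.6% against 54.2% (54.3% under quantile normalization), with the median model at 0.49 and 0.06. Without eye replicate 1 the second count was 1394.

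The Ueno and Taira libraries of the 13 female tissues were compared with tissue as a block. Genes were named here only if they went the same way in all 13 tissues, so that agreement is the naming rule. Of the called models, 141 of 216 higher and 1228 of 3307 lower ones went the same way in all 13. Higher in Ueno in 13 of 13 tissues were smad4.1.S, a signalling gene, the cell cycle inhibitor cdknx.S, the smooth muscle gene tagln.L, the mitochondrial ribosome genes mrpl55-like.L and dap3.L, and crebl2.1, by 1.31 to 1.88. With a pseudocount of 5 the crebl2.1 difference, 0.92, was under the threshold of 1. The gene dap3.L stood at 69.2 ± 51.8 TPM in Ueno and 24.8 ± 11.1 TPM in Taira (SD, n = 13 tissues, adjusted p = 8.33e-05). Lower in 13 of 13 tissues were the immunoglobulin gene ighx.L, cebpz.L, the myosin myh9.S, epb41l2.L, mphosph10.L and the translation factor eif5b-like.S, with differences of -2.98 to -2.71. The myosin gene myh9.S stood at 19.3 ± 25.3 TPM in Ueno and 120 ± 98.0 TPM in Taira (adjusted p = 8.09e-05). Each side of this comparison is 1 frog and 1 dataset, so the p-values measure how alike the 13 tissues were, not how frogs vary.

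Cytosolic ribosomal protein genes had a median of 0.40 over 59 models and a positive median in 13 of 13 tissues (3 called higher, camera adjusted p = 5.08e-22). Oxidative phosphorylation genes had a median of 0.54 over 91 models and a positive median in 12 of 13 (9 called higher, camera adjusted p = 1.2e-29). The complement and interferon response list was negative (10 of 46 models called lower, camera adjusted p = 0.00674), as were the endothelium list (8 of 23, camera adjusted p = 0.0143) and the spleen list (4 of 38, camera adjusted p = 0.00214). With an estimated correlation each of these 5 had an adjusted p = 0.841, and counts adjusted over the list alone were the same. After median-of-ratios scaling 25 ribosomal protein models and 45 oxidative phosphorylation models were called higher. The mitochondrial ribosomal protein list (median 0.15, 1 of 71 models higher and 2 lower, camera adjusted p = 1.63e-05), the proteasome list (4 of 63 lower, camera adjusted p = 0.00685) and the homeobox cluster list (none of 49 called, camera adjusted p = 0.00954) also passed as higher, although the proteasome and homeobox medians, -0.12 and -0.02, were negative and turned positive after scaling. The homeobox list did not pass after scaling (adjusted p = 0.156). These 3 were lost as well with an estimated correlation (adjusted p = 0.841). Over all models, 216 were higher and 3307 lower in Ueno, and the median model stood at -0.22. After median-of-ratios scaling 1350 were higher and 1475 lower with a median of -0.02, so the share higher went from 6.13% to 47.8%. Under quantile normalization the counts were 745 and 1222 (37.9%). With a pseudocount of 0.1 the counts were 460 and 6622, and with 5 they were 100 and 839. The testis libraries, from other animals and not in this fit, moved the same way for 87% of the higher and 97.9% of the lower models, against 18.8% and 75% of all models.

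**Figure D4:**
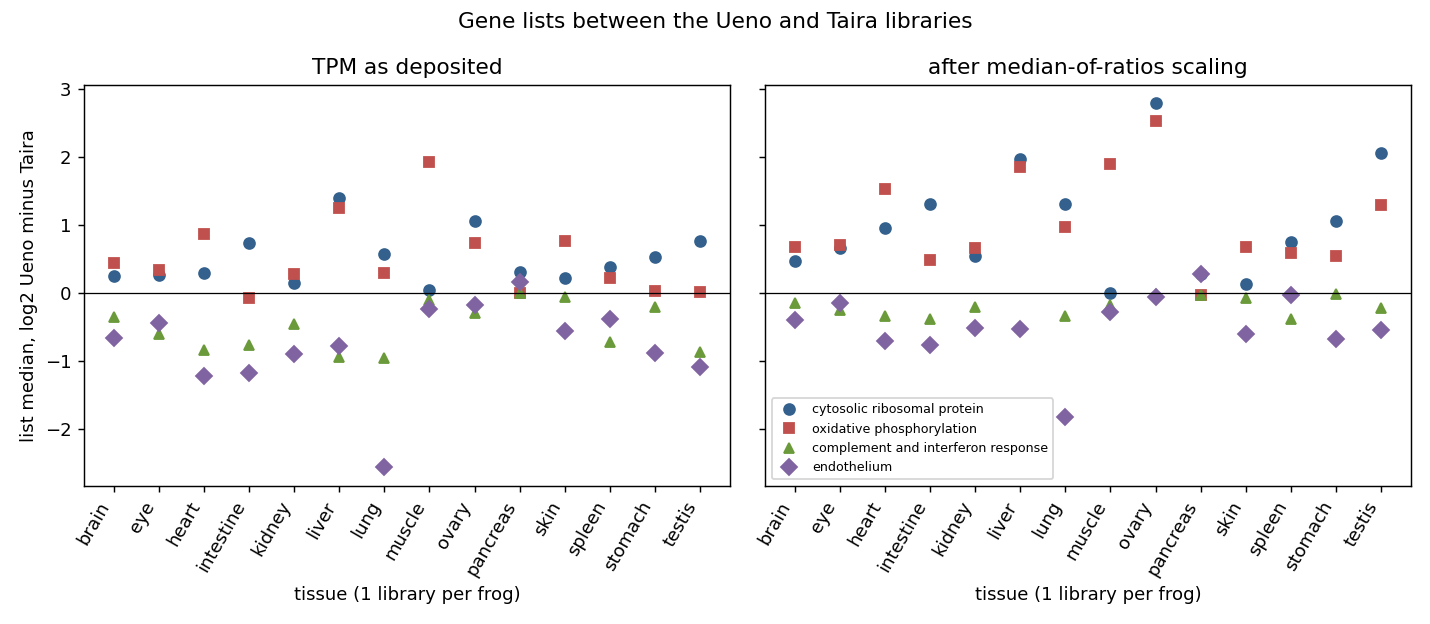
Median log2 difference, Ueno minus Taira, of 4 gene lists (symbols) in each of the 14 tissues (x axis), 1 library per dataset and tissue, from TPM as deposited (left) and after median-of-ratios scaling (right). The ribosomal protein medians lie above 0 in every tissue, from 0.04 in muscle to 1.40 in liver as deposited.

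The next question was how the L and S copies of a gene share its expression. Among 7749 tested pairs the L copy was higher in 1205 and the S copy in 635, so L made up 65.5% of the calls (exact binomial 95% interval 63.3 to 67.7). Of these, 981 and 517 differed by at least 1 in each dataset taken alone. The outer membrane channel gene vdac3 averaged 235 TPM from L and 0.197 TPM from S over the 28 libraries (log2 ratio 7.06, SE 0.15, adjusted p = 8.76e-18). The genes ndufv2, fkbp11, eef2.2, vma21, plbd2, rhoc and dnaja4.1 were also higher from L in 28 of 28 libraries, and the S copies of ndufv2 and vma21 were listed at 0 in all of them, as the L copies of myeov2 and sdhc were. The ribosomal protein gene rpl39 averaged 1085 TPM from S and 0.476 TPM from L (log2 ratio -9.32, SE 0.53, adjusted p = 9.08e-12). The genes myeov2, sh3bgrl3, sdhc, sdsl, rpl38, mpc1 and sf1 were also higher from S in 28 of 28 libraries. The median log2 ratio of L to S was 0.16 over all pairs. All 14 tissues had more pairs with a higher L than a higher S copy, from 1.30 times as many in ovary to 1.92 times in eye. L copies held between 50.8% and 66.9% of the TPM of pairs, with liver at 66.8% ± 0.164 (SD, n = 2). This share weighs abundant genes most. Over all tested pairs the median log2 ratio in the liver libraries was 0.006 and 0, with 1.57 times as many L as S calls. Pairs hardly expressed in liver pull this median to 0. Over the 5225 pairs whose copies summed to a mean TPM of at least 1 in liver it was 0.204 and 0.143. The same measure ran from 0.108 to 0.307 over the 28 libraries. L and S copies are similar in sequence, so reads that fit both copies were divided by the authors' estimation, and pairs with near-identical copies are uncertain. With a pseudocount of 0.1 the counts were 1944 and 1014, and with 5 they were 578 and 322.

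**Figure D5:**
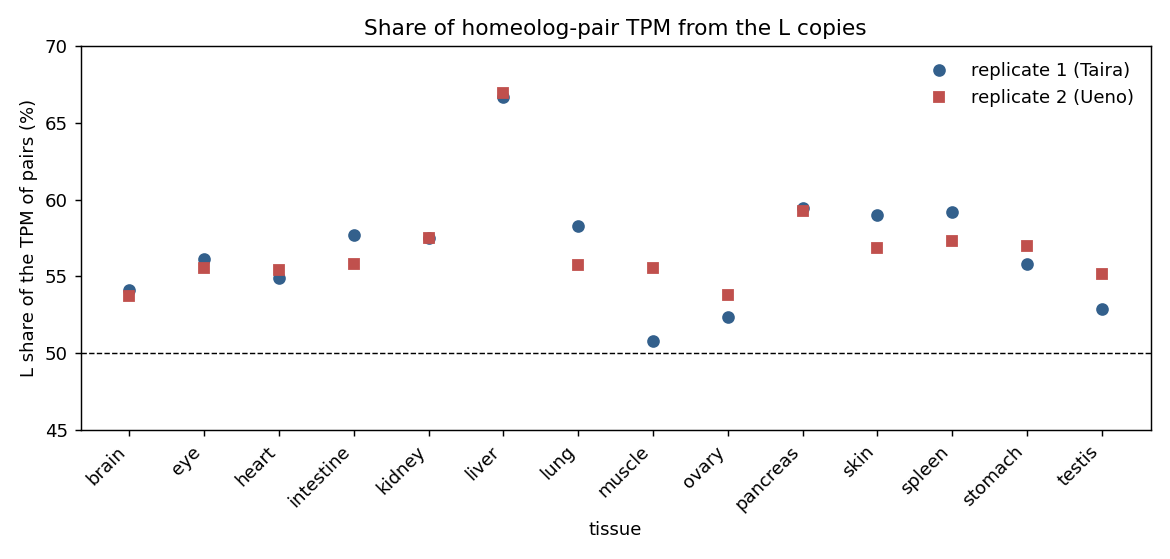
Share of the TPM of homeolog pairs that came from the L copies (y axis, %) in each tissue (x axis), 1 circle for replicate 1 and 1 square for replicate 2, with a dashed line at 50% and a y axis that starts at 45%. All 28 libraries lie above the line, between 50.8% and 66.9%.

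The ratio of L to S, with 1 TPM added to each copy, differed between tissues for 6239 of 7749 pairs (80.5%, limma F test). With a silent copy this ratio follows the level of the other copy. The gene ndufv2, with S at 0 in all 28 libraries, passed the F test (adjusted p = 1.08e-05), as did vma21 (adjusted p = 0.000152). The 80.5% thus includes pairs whose level alone varied, and does not count changed use of the copies. In 988 pairs L was higher by more than 1 in 1 tissue and S in another, in both libraries of each. The water channel aqp8 came from L in skin (2461 ± 383 TPM, S at 0.085 TPM) and from S in intestine (495 ± 189 TPM, L at 19.3 TPM), a swing of 17.19 (adjusted p = 3.81e-09). The protease mep1a came from L in intestine (1620 ± 749 TPM) and from S in kidney (61.3 ± 9.19 TPM, L at 1.37 TPM). The adhesion gene cdh1 came from S in intestine (356 ± 222 TPM, L at 0.055 TPM), and in testis L stood at 17.5 ± 5.66 TPM against 0.850 TPM from S. Profiles of the copies over the 14 tissues were nevertheless alike for most pairs, with a median Pearson's r of 0.841 over 7646 pairs, 0.839 in the Taira and 0.831 in the Ueno libraries, against 0.261 for randomly paired L and S models. In 34.4% of pairs r was above 0.9, against 1.22% of random pairings, and it was below 0 in 2.49%.

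Gene groups differed in how often a symbol was listed with both endings. Of the symbols, 8017 were listed with L and S (52.8%), 5431 with L only (35.8%) and 1725 with S only (11.4%). A copy missing by name need not be lost, since 20523 models had no symbol and 1343 had another ending. Signalling ligand and receptor genes were listed with both in 85.9% of cases (Fisher's exact test, adjusted p = 2.65e-08) and homeobox cluster genes in 92.1% (adjusted p = 2.63e-06). Shares were 100% for the muscle list (adjusted p = 0.00131) and for the fibroblast and matrix list (adjusted p = 0.0105), 88.2% for heart (adjusted p = 0.0122), 84.2% for skin (adjusted p = 0.0204), 83.9% for cytosolic ribosomal proteins (adjusted p = 0.00243), 78.4% for oxidative phosphorylation (adjusted p = 0.00134) and 75% for the proteasome (adjusted p = 0.0244). DNA replication and repair genes went the other way, with both listed in 17.9%, 47 symbols with only L and 8 with only S (adjusted p = 7.28e-08). No list departed from the others in the direction of its L and S calls after adjustment over 33 lists by Fisher's exact test, the lowest adjusted p being 0.809. The oxidative phosphorylation list had 15 pairs higher from L and 12 from S, and the cytosolic ribosomal protein list 4 and 7 (exact p = 0.0554 before adjustment).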

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

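The test weighed in this part was chosen before its result was seen, but its reading for silent copies alone was chosen after. The ratio of L to S, with 1 TPM added to each copy, differed between tissues for 6239 pairs by limma's F test. That count includes pairs whose level alone varied, such as ndufv2 with S at 0 in all libraries. A higher L copy in 1 tissue and a higher S copy in another, in both libraries of each, was seen in 988 pairs. The 8 named pairs with the widest swings of the log2 ratio were aqp8 (17.19, L in skin and S in intestine), mep1a (15.28, L in intestine and S in kidney), mmp1 (14.98, L in intestine and S in spleen), car1_predicted (13.83, L in brain and S in testis), agxt (13.32, L in kidney and S in testis), ca13 (12.51, L in lung and S in intestine), cdh1 (11.66, L in testis and S in intestine) and ca4 (11.60, L in lung and S in intestine). Some rest on uneven libraries: the S copy of mmp1 stood at 77.8 ± 80.9 TPM in spleen, and ca4 at 66.5 ± 79.6 TPM from L in lung and 609 ± 714 TPM from S in intestine. The S copy of car1_predicted stood at 2721 ± 2569 TPM in testis, and its L copy at only 12 TPM in brain. For agxt, S stood at only 6.05 TPM in testis against L at 6109 TPM in kidney. Both swings thus come mostly from 1 abundant copy in 1 tissue (log2 ratios 10.83 and -2.49 for agxt, 3.27 and -10.56 for car1_predicted).

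More pairs were called with a higher L copy than with a higher S copy, 1205 against 635. Silent S copies could give such a surplus, which would then vanish among pairs with both copies expressed. Among 3588 pairs whose copies both averaged at least 5 TPM, L made up 63.9% of the calls (exact binomial 95% interval 60.4 to 67.2, 506 against 286). The surplus was thus not confined to pairs with an S copy silent throughout. The minimum itself leaves such pairs out, and a copy that passes it can still be silent in some tissues. How much silent copies add to the whole surplus therefore cannot be told. Poorly modelled S copies can pass that minimum and stay open, as do the division of reads that fit both copies and a difference in transcript length, neither of them tested, beside a difference between the subgenomes.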

How the results depend on the processing

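The added alternatives, without skin, without liver, without kidney models highest in an ovary library and without eye models also higher in muscle or skin, were chosen after seeing the data. The 223 named results were run under 8104 alternatives, of which 8070 kept direction and side of the threshold, 22 passed it newly, 2 no longer passed and 10 reversed. Most named results were picked for the largest differences, and many alternatives left out 1 library of another tissue. That stability is therefore largely built in and says little about the counts. Without a filter, with a TPM minimum of 5, without a variance trend and with testis added, every count stayed within 1.5 times. So did the added ones, 265 and 3834 higher and lower in Ueno without skin, 155 and 3097 without liver, 3830 in kidney and 4477 in eye. Depth is unknown, so what it limits could not be stated. The cause was not tested for any value below, except that a larger pseudocount shrinks differences of low genes by construction.

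With a pseudocount of 0.1, 419 models were higher in pancreas, 460 higher and 6622 lower in Ueno, 1944 pairs were higher from L and 1014 from S, and the median profile r was 0.8324. With 5, counts were 7849 in brain, 3156 in eye, 2645 in kidney, 1785 in lung, 167 in pancreas, 1706 in skin, 3244 in spleen, 722 in stomach, 2786 for testis over ovary, 1821 for heart over muscle, 343 for stomach over intestine, 100 and 839 higher and lower in Ueno, and 578 and 322 for L and S. After median-of-ratios scaling they were 5888 in brain, 2377 in kidney, 2825 in liver, 3778 in muscle, 1513 in pancreas, 3272 in spleen, 2141 in stomach, 1876 for heart over muscle, 1759 for muscle over heart, 999 for stomach over intestine, 2986 for brain over eye, and 1350 and 1475 in Ueno. Under quantile normalization they were 5351 in brain, 3807 in eye, 2455 in kidney, 2747 in liver, 3467 in muscle, 1856 in pancreas, 2315 in stomach, 1744 for heart over muscle, 1554 for muscle over heart, 1148 for stomach over intestine, 1723 for intestine over stomach, 3325 for brain over eye, and 745 and 1222 in Ueno. With both copies past the minimum the median profile r was 0.8508.

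With an estimated correlation 25 lists passed in tissues, 8 in organ pairs and 0 between the frogs, where fry called 19 and the preset correlation 8. With the frog as a block 5301 models were higher in heart than in muscle, irf4.S in spleen passed, lists past the test went from 275 to 285 in tissues (17 gained and 7 lost) and from 45 to 50 in organ pairs (5 gained), and no other call of a named gene changed. The block raised the count of higher models in every tissue and both counts of every organ pair. Intestine over stomach went from 2659 to 3862 and brain over eye from 5173 to 6671.

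Leaving out 1 library gave 1386 (without heart replicate 1) to 2836 in heart, 2276 (intestine 1) to 3792 in intestine, 2669 (kidney 1) to 5077 in kidney, 1237 (lung 1) to 3020 in lung, 1204 (muscle 2) to 1950 in muscle, 1683 (skin 2) to 2858 in skin, 2798 (spleen 1) to 5769 in spleen, 770 (stomach 1) to 1353 in stomach and 3975 (testis 1) to 7539 in testis. It gave 2935 (testis 1) to 6769 for testis over ovary, 1471 (heart 1) to 3894 for heart over muscle, 1671 (intestine 1) to 2947 for intestine over stomach and 1394 (eye 1) to 2229 for eye over brain. Uncalled genes changed sign around 0: myh7.S (heart) at -0.082 with a pseudocount of 5, -0.034 without the gonads and -0.008 to 0.115 over left-out libraries, sult1c2.1 (stomach) at -0.133 with a pseudocount of 5 and -0.23 without the gonads, rpe65.S (eye) at -0.072 and fshr.L (ovary) at 0.089 under quantile normalization, ankrd1.L (heart) at -0.515 (without heart replicate 1) to 1.107 and ttr.S (liver) at -0.219 (without liver replicate 1) to 0.45.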

Other observations

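The test of the donor females and all 4 tests of the kidney were chosen only after the results were seen. Lists of shared cell machinery and cell types differed between tissues too. Ciliated cell genes rose in 13 of 17 models in testis (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.16e-06, and adjusted p = 0.102 with an estimated correlation). In ovary, mitochondrial ribosomal protein genes rose in 55 of 71 models (56 adjusted over the list alone, camera adjusted p = 4.09e-09, and adjusted p = 0.341 with an estimated correlation) and spliceosome genes in 33 of 48 (33 adjusted over the list alone, camera adjusted p = 5.2e-08, and adjusted p = 0.109 with an estimated correlation). Proteasome genes rose in 34 of 63 models in testis and fell in 6 (35 and 6 adjusted over the list alone, camera adjusted p = 2.51e-05, and adjusted p = 0.361 with an estimated correlation). Glycolysis genes rose in 8 of 16 models in eye and fell in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.0482, and adjusted p = 0.303 with an estimated correlation). Signalling genes rose in 41 of 132 models in eye (44 adjusted over the list alone, camera adjusted p = 0.00907, and adjusted p = 0.719 with an estimated correlation). The translation initiation list was lower in brain relative to other models (camera adjusted p = 0.00206, and adjusted p = 0.553 with an estimated correlation), with a median of -0.05 (-1.21 after median-of-ratios scaling and -1.01 under quantile normalization), a mean of 0.16, 9 of 52 models higher and 2 lower (8 and 1 adjusted over the list alone). The adipocyte list passed in neither eye nor kidney, with 3 of 11 models higher in each (3 adjusted over the list alone, camera adjusted p = 0.728 and 0.0973).

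The livers of the frogs differed in genes of the liver list, with 1 library each and so no replicate check. Of 35 liver list models, 21 were lower by at least 1 in the Ueno liver, 1 was higher (apoa1.L) and 13 lay within 1, while of all 33317 models 19.1% were lower by at least 1 and 7.51% higher. A model under 1 TPM in the Taira liver cannot be lower by 1 on this scale, and only 19200 models reached 1 TPM there. The 19.1% thus understates the share among expressed models, and the contrast with the list is smaller than it looks. In the Ueno liver the median was higher by 1.40 for cytosolic ribosomal protein genes and by 1.26 for oxidative phosphorylation genes, and the share of TPM from ribosomal protein genes was 9.81% against 3.06%. The fibrinogen gene fga.L stood at 5131 TPM in the Taira and 115 TPM in the Ueno liver, the lipoprotein gene apob.L at 464 and 11.3 TPM and the bile acid enzyme gene cyp7a1.L at 79.2 and 0.93 TPM. The prothrombin gene f2.L stood at 1031 and 1535 TPM, and proc.S at 418 and 413 TPM. These genes were chosen after their values were seen, and RNA quality was not compared between the livers.

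In the Ueno libraries 216 models were higher and 3307 lower. Of 100 exchanges of the libraries within tissues only 1, the real one, gave as many calls (3523 against at most 2331, where 1 tissue was exchanged), but the tissues of a side share 1 female, so this shows that they moved alike and cannot speak to chance between animals. Median-of-ratios scaling left 1.09 lower calls per higher call (1350 higher and 1475 lower), and quantile normalization 745 higher and 1222 lower, but both bring the median model near 0, so the scaled splits cannot tell whether scaling made the split uneven. A difference of the donor females alone is argued against by testis, from other animals, which moved the same way for 97.9% of the lower models against 75% of all models. Clutch, collection date and dataset cannot be told apart, because each clutch was a dataset of its own. A biological difference between the clutches stays open and untested, and RNA quality and library preparation of the datasets were not compared.

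Oocyte transcripts stood in both kidney samples. Of 101 transcripts abundant in ovary and under 1% of it in the 12 other tissues, all 101 were above 0 in each kidney, and 97% in the Taira and 90.1% in the Ueno frog lay within 4-fold of the median kidney to ovary ratio, so ovary RNA carried into the kidney samples is a candidate explanation. With the ovary of the other frog the share was 79.2% for the Taira and 91.1% for the Ueno kidney, so this measure does not single out a frog's own ovary. Spillover of reads into every library is argued against, because over 36 members of the ovary list the next highest tissue reached at most 10.1% of the kidney median. Separate expression of each gene by cells of the Taira kidney is argued against, since 92.1% of its ratios to its own ovary (exact binomial 95% interval 85 to 96.5) lay within 1.5-fold of their median, against 27.2% of 2150 other models abundant in ovary and 21.8% of its ratios to the Ueno ovary. For the Ueno kidney the share was 60.4% with the Taira ovary (50.2 to 70, other models 23.3%) but 32.7% with its own (23.7 to 42.7, other models 25%), so kidney expression and the source stay open there, and whether oocytes lay within either kidney was not tested.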
